A study of Mus musculus with 8 samples.

How the data were processed

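Gene expression was measured by sequencing of polyadenylated RNA (TruSeq Stranded mRNA libraries from total RNA) in 8 libraries: mouse embryonic stem cells that carry β-catenin or lack it by knock-out, each with DMSO or CHIR99021 for 72 hours, 2 libraries per group. The authors deposited a table of expected counts, the estimated reads per Ensembl gene that kallisto gives (version not stated), with genome build GRCm38.p4 per the labels. It holds 48440 genes and 1 column per library, not normalised; 36.9% to 38.4% of the entries of a library were not whole numbers, as estimated counts are. The transcript set, the way transcripts were summed to genes and the strand setting of the counting are not stated. Columns were matched to libraries by their titles, and each sample's group came from the labels. Chromosome, start, end and strand came from the GENCODE M21 annotation of GRCm38, matched on the gene identifier without its version for 17680 of the 17739 tested genes. No sequence reads were reprocessed.

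Estimated counts were rounded to whole numbers. Genes were kept with edgeR 4.0.16 filterByExpr by group (at least 10 counts, 15 in total), which left 17739 genes holding 99.905% to 99.918% of the counts of each library. Library sizes were scaled by the trimmed mean of M values (factors 0.9857 to 1.0181), and a quasi-likelihood model with 1 mean per group was fitted to all 8 libraries, which leaves 4 residual degrees of freedom. The 5 comparisons were CHIR99021 against DMSO in parental cells and in the knock-out, knock-out against parental cells in DMSO and in CHIR99021, and the interaction, each with the quasi-likelihood F test, 2-sided, and Benjamini-Hochberg adjustment over all genes tested at 0.05. SE is the absolute log2 fold change divided by the root of F, and CPM are counts divided by the scaled library size, as edgeR gives them. The common biological coefficient of variation was 0.0532. Totals of 23650572 to 27680649 counts per library set the precision: 10 counts correspond to well under 1 CPM, and replicates of a group differed by 3.54 to 5.36 times the variance of counting alone (chi-square per degree of freedom). Ratios for genes with few counts carry exact 95% intervals from the binomial split of the summed counts.

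Before the data were examined, 36 gene lists with 733 gene symbols were written for pluripotency states, germ layers and other cell types, signalling pathways, metabolism, stress and the cell cycle; a list needed 4 measured members to be tested, which 35 had. Each was tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Of 175 list tests 74 passed with the preset correlation and 9 with the estimated one: Wnt/β-catenin targets in 3 comparisons and others as given beside each result. The estimated setting also takes its p from the 4 residual degrees of freedom, so a lost call need not come from correlation between genes. For the Nodal/Activin list in the interaction the estimated correlation, -0.038, lay below the preset one, yet adjusted p went from 1.31e-05 to 0.0765. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. For each list the members called over all genes, and those adjusted over the list alone, are given. Lists share members, such as T, Cdx2 and Eomes, so their results are not separate.

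Genes named in the text follow a rule set at the same time: Ctnnb1 in each library and Gsk3a, Gsk3b, Jup, Tcf7, Tcf7l1, Tcf7l2, Lef1, Axin2, T, Cdx1, Sp5, Nanog, Esrrb, Pou5f1, Sox2 and Klf4 in each comparison; the 8 highest and 8 lowest log2 fold changes of a comparison (5 and 5 for the knock-out against parental cells in CHIR99021) among called genes with at least 5 CPM in the higher group, libraries that do not overlap between groups and a name that is not a clone name; up to 4 members of a list with the smallest adjusted p; and other members of reported lists as values. Some genes that the rule names are not reported here. Eomes in the plot of single libraries comes under the rules on fold changes and on lists. Of the 144 genes so named 40 overlap another tested gene in the annotation, 31 of them on the opposite strand, among them Patl2 with B2m, Ctsb with Fdft1 and Col4a1 with Col4a2; with the strand setting unknown, reads may be shared within such pairs.

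Alternatives were DESeq2 1.42.0 (Wald test), limma-voom, relative log expression size factors, no filter beyond 1 read, a stricter filter (5 CPM in 2 libraries), the compared groups alone, a replicate block, an adjusted p under 0.01, a fold change over 2, and leaving out each of the 8 libraries in turn. In the last, the lone library of a group is assumed to vary like those of the other groups. One alternative, without the genes of distal chromosomes 1 and 2, was chosen after seeing the data. The procedure was tried on simulated data with the totals and spread of these libraries. The changed genes were drawn only from those with at least 50 counts expected in a library of mean size. The shares recovered therefore do not cover genes with fewer counts, such as Lef1. Of 50 genes changed 2-fold, it recovered 44, 46, 44 and 47 in the 4 comparisons of groups and 38 in the interaction. Of 50 changed 1.25-fold, it recovered 16 to 21 in the former and 9 in the latter. There were 15 to 24 false calls among 17389 to 17419 genes. The 24 were for CHIR99021 in the knock-out, beside 16, 38, 46 and 50 genes recovered at folds of 1.25, 1.5, 2 and 4. In each comparison false calls were a larger share of all calls than the adjusted p threshold aims at. R 4.3.3 was used throughout, with figures drawn in matplotlib 3.10.9.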

Results

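Messenger RNA was sequenced from mouse embryonic stem cells of the 129/Ola background that were parental (CTNNB1+/+) or knock-out for β-catenin, the protein encoded by Ctnnb1. Each line was kept for 72 hours with CHIR99021, an inhibitor of the kinase GSK3, at 3 μM or with its vehicle DMSO at 0.3 μl/ml, in serum medium on gelatin without feeder cells. The 4 groups had 2 libraries each. The total of estimated counts per library ran from 23650572 in parental cells with DMSO, replicate 1, to 27680649 in knock-out cells with CHIR99021, replicate 1. Levels are given as CPM, the counts of a gene scaled to a common library total. The correlation across genes between the replicates of a group, on log2 CPM, was 0.9866 to 0.9894. On the first principal component, with 32.6% of the variance, the parental libraries with CHIR99021 lay at 46.42 and 47.93 and the other 6 libraries between -24.72 and -9.17. On the second, with 17% of the variance, the parental libraries with DMSO lay at 28 and 33 and the knock-out libraries with CHIR99021 at -25.68 and -25.19. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Genotype and line coincide in this design. A difference between the lines, in level or in response, may therefore come from β-catenin or from something else that sets them apart.

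The knock-out was visible in the transcript itself. Ctnnb1 (ENSMUSG00000006932, chromosome 9, 120929216 to 120960507, GRCm38) was at 896.5 ± 12.8 CPM (SD, n = 2) in parental cells with DMSO and 828.5 ± 21.3 CPM (SD, n = 2) with CHIR99021. It was at 9.35 ± 1.94 CPM (SD, n = 2) in the knock-out with DMSO and 9.06 ± 0.509 CPM (SD, n = 2) with CHIR99021, which is 1.04% and 1.09% of the parental level. The 4 parental libraries ran from 813.4 to 905.6 CPM and the 4 knock-out libraries from 7.98 to 10.72 CPM. CHIR99021 gave Ctnnb1 a log2 fold change of -0.11 ± 0.06 (SE; adjusted p = 0.245) in parental cells, where the adjusted p was 0.024 with no filter on low counts and 0.0458 with the compared groups alone. In the knock-out the value was -0.04 ± 0.11 (adjusted p = 0.871).

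**Figure D1:**
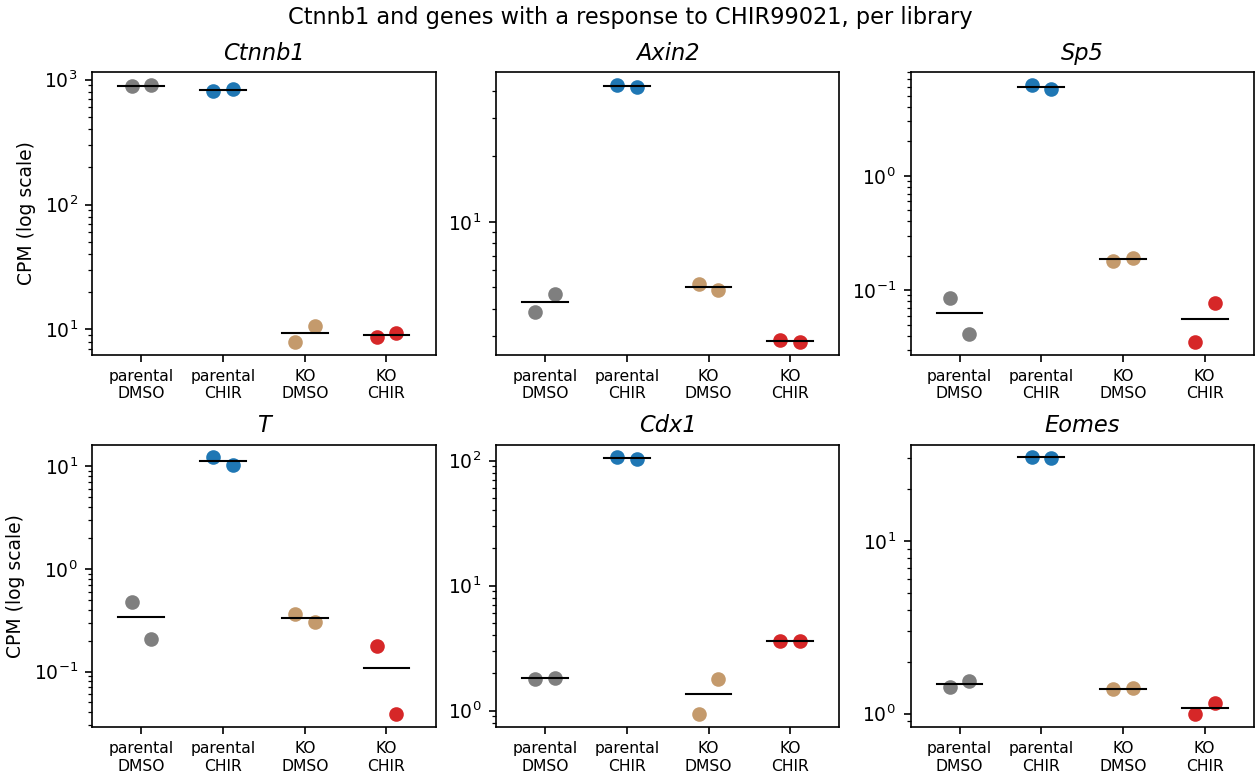
CPM, on a log scale, of Ctnnb1 and 5 genes with a response to CHIR99021 in each of the 8 libraries; points are libraries and lines are group means. Ctnnb1 was at 7.98 to 10.72 CPM in the knock-out libraries, and Axin2 rose with CHIR99021 in parental cells from 4.28 to 42.0 CPM and fell in the knock-out from 5.01 to 2.85 CPM.

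The first comparison asked what GSK3 inhibition does where β-catenin is present. In parental cells CHIR99021 raised a set of Wnt/β-catenin targets and mesoderm regulators from low levels. Cdx1 (ENSMUSG00000024619, chromosome 18, 61018862 to 61036199), a homeobox gene of the posterior body axis, went from 1.82 ± 0.0163 to 104.6 ± 2.33 CPM (SD, n = 2 each), a log2 fold change of 5.84 ± 0.13 (SE). Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), a negative regulator of the Wnt pathway and one of its common reporters, went from 4.28 ± 0.583 to 42.0 ± 0.686 CPM (SD, n = 2 each), a log2 fold change of 3.29 ± 0.09. The T-box gene Eomes (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132) went from 1.48 ± 0.0834 to 30.4 ± 0.0707 CPM (SD, n = 2 each), a log2 fold change of 4.36 ± 0.11. T, also named Brachyury (ENSMUSG00000062327, chromosome 17, 8434423 to 8442496), went from 0.34 ± 0.187 to 11.3 ± 1.34 CPM (SD, n = 2 each), a log2 fold change of 5.05 ± 0.31. Their adjusted p ran from 1.06e-09 for Cdx1 to 9.92e-07 for T.

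Some of these folds rest on few counts in the DMSO libraries, so they are given as ratios of summed counts with a 95% counting interval, which covers counting error only. Sp5 (ENSMUSG00000075304, chromosome 2, 70474923 to 70477729), a zinc-finger target of Wnt signalling, had 300 counts with CHIR99021 and 3 with DMSO, a ratio of 94.8 (32.1 to 462). The homeobox gene Nkx1-2 had 547 and 11 counts, a ratio of 47.1 (26.1 to 94.9), and Dmgdh, a mitochondrial dehydrogenase of choline breakdown, had 533 and 8, a ratio of 63.1 (31.8 to 147). Their fitted log2 fold changes were 6.46, 5.53 and 5.94. The ion channel gene Trpm1 rose by a log2 fold change of 3.85 ± 0.09 and Nt5e, which encodes the ecto-enzyme CD73, by 3.57 ± 0.16.

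Among the genes with the lowest fold changes, Enpp3, an ecto-nucleotide hydrolase, fell from 10.2 ± 0.774 to 0.819 ± 0.0342 CPM (SD, n = 2 each), a log2 fold change of -3.62 ± 0.14. The others were Bcl11a at -3.39 ± 0.29, Slc27a2, a fatty-acid transport protein, at -3.21 ± 0.21, Sox21 at -2.62 ± 0.21, the Hedgehog-binding Hhip at -2.53 ± 0.20, Gfod1 at -2.38 ± 0.20, the endocytic receptor Lrp2 at -2.34 ± 0.07 and Crmp1 at -2.28 ± 0.11. Of the nuclear partners of β-catenin, Tcf7 rose by 0.73 ± 0.06 and Tcf7l1 and Tcf7l2 fell by 1.06 and 0.46 on the log2 scale. Lef1 was at 0.55 ± 0.133 CPM with DMSO and 0.543 ± 0.118 CPM with CHIR99021 (SD, n = 2 each), too few counts for a change to be detectable (log2 fold change -0.02 ± 0.57). Gsk3a at 0.02, Gsk3b at -0.05, Jup at -0.02 and Esrrb at -0.01 passed no test (SE 0.04 to 0.05; adjusted p 0.534 to 0.927).

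Gene lists fixed before the data were examined show which programmes these genes belong to. Of the 20 measured Wnt/β-catenin targets (26 listed), 9 rose and 4 fell (adjusted p = 2.56e-15, and adjusted p = 0.0293 with an estimated correlation), and adjusted over the list alone 10 rose and 5 fell. Besides those above, Wls, which carries Wnt proteins to the cell surface, rose by 1.21 ± 0.10 and Cdx2 by 3.83 ± 0.71, while Ccnd2, which encodes cyclin D2, fell by 1.19 on the log2 scale. Among 15 measured genes of the primitive streak and early mesoderm (25 listed) 5 rose and 1 fell, as they did adjusted over the list alone (adjusted p = 4.9e-06, and adjusted p = 0.0539 with an estimated correlation). The trophoblast list gave 5 higher and 3 lower of 14 (adjusted over the list alone 6 and 3; adjusted p = 0.0012, and adjusted p = 0.0811 with an estimated correlation). Its members Cdx2 and Eomes are also on the streak or target lists. Krt8 rose by 0.85 ± 0.07 and Tead4 by 0.47 ± 0.05, and Gata2 fell by 1.08 on the log2 scale.

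Pluripotency genes split. Of 16 general pluripotency genes 14 fell and none rose (adjusted over the list alone, 15 fell; adjusted p = 5.18e-19, and adjusted p = 0.0336 with an estimated correlation), by small amounts: Sall1 by 0.52, L1td1 by 0.51, Dppa2 by 0.54, Dnmt3l by 0.68 and Sox2 by 0.38 on the log2 scale. Pou5f1, which encodes OCT4, went from 1548 ± 29.7 to 1414 ± 35.4 CPM (SD, n = 2 each), a log2 fold change of -0.13 ± 0.04 (adjusted p = 0.0358). That call was lost without parental DMSO replicate 1 (adjusted p = 0.214), DMSO replicate 2 (0.1), CHIR99021 replicate 1 (0.0607) or CHIR99021 replicate 2 (0.17), or without knock-out CHIR99021 replicate 1 (0.0562). The 22 naive pluripotency genes went both ways, with 5 higher and 9 lower (adjusted over the list alone 6 and 10; adjusted p = 0.123). Tfcp2l1 rose by 0.69 ± 0.03, the threonine dehydrogenase gene Tdh by 0.60 ± 0.04 and Klf4 by 0.25 ± 0.04, while Fgf4 fell by 0.82, Tcl1 by 0.65 and Nanog by 0.19 on the log2 scale. Formative and primed epiblast genes gave 1 higher and 11 lower of 17 (adjusted over the list alone 2 and 12; adjusted p = 7.72e-08, and adjusted p = 0.0568 with an estimated correlation). Dnmt3a, a DNA methyltransferase, fell by 1.05, Fgf15 by 1.41, Pou3f1 by 1.46 and Grhl2 by 1.47.

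Several other programmes moved in parental cells. Of 12 measured neural ectoderm genes (27 listed) 7 fell and 1 rose, as they did adjusted over the list alone (adjusted p = 4.9e-06, and adjusted p = 0.0568 with an estimated correlation). Tubb3 fell by 1.13, Nes by 1.28 and Ncam1 by 0.997 on the log2 scale. The Nodal/Activin response gave 8 lower and 1 higher of 12, also adjusted over the list alone (adjusted p = 1.71e-08, and adjusted p = 0.0362 with an estimated correlation). Its members Lefty1, an inhibitor of Nodal, Tdgf1, its co-receptor, and Skil fell by 1.85, 0.47 and 0.56. In the FGF/ERK response 9 of 19 fell and 3 rose (adjusted over the list alone 10 and 3; adjusted p = 0.0203, and adjusted p = 0.176 with an estimated correlation), with Dusp4 lower by 1.41 and Etv1 by 0.97. Genes of sterol synthesis moved one way: 15 of 24 rose and none fell (adjusted over the list alone, 16 rose; adjusted p = 7.41e-06, and adjusted p = 0.209 with an estimated correlation), among them Ebp by 0.90 ± 0.07 and Fdft1 by 0.41 ± 0.04.

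Lysosome and autophagy genes, the set controlled by TFEB and its relatives, had 12 of 30 higher and 5 lower (adjusted over the list alone 14 and 5; adjusted p = 0.0012, and adjusted p = 0.0811 with an estimated correlation); the protease gene Ctsl rose by 0.65 ± 0.04 and Rragd by 0.87 ± 0.07. The p53 response gave 7 higher and 1 lower of 20 (adjusted over the list alone 7 and 2; adjusted p = 0.00235, and adjusted p = 0.177 with an estimated correlation). Its largest change was in Cdkn1a, which encodes the cell-cycle inhibitor p21, at 1.68 ± 0.06, and Ccng1 rose by 0.46 ± 0.06. Among 22 genes of G2/M and mitosis 7 fell and none rose, also adjusted over the list alone (adjusted p = 0.0105, and adjusted p = 0.296 with an estimated correlation). Nusap1 was at -0.39 ± 0.04 and Top2a at -0.27 ± 0.04. Primitive and extraembryonic endoderm genes gave 8 lower and 4 higher of 23, also adjusted over the list alone (adjusted p = 0.00191, and adjusted p = 0.219 with an estimated correlation), with Sox7 lower by 1.57 and Apoe higher by 0.64 ± 0.05. Of 21 basement membrane and extracellular matrix genes 11 fell and 4 rose, also adjusted over the list alone (adjusted p = 0.0152, and adjusted p = 0.371 with an estimated correlation; adjusted p = 0.0732 without parental CHIR99021 replicate 2). Col4a1, a chain of collagen IV, fell by 1.14 on the log2 scale and Lama5, a laminin chain, rose by 0.88 ± 0.04. The interferon response had 6 of 12 higher (adjusted over the list alone 6 higher and 1 lower; adjusted p = 0.0488, and adjusted p = 0.209 with an estimated correlation), B2m among them at 0.62 ± 0.08 and H2-K1 at 0.49 ± 0.07. The call on this list was lost without 6 of the 8 libraries in turn, with adjusted p = 0.0738 and 0.0764 without parental DMSO replicates 1 and 2, 0.112 without parental CHIR99021 replicate 2, 0.0741 and 0.0636 without knock-out DMSO replicates 1 and 2, and 0.0561 without knock-out CHIR99021 replicate 1.

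Over all 17739 genes tested, CHIR99021 changed 3441 in parental cells at an adjusted p under 0.05 (edgeR), 1614 higher and 1827 lower, of which 558 changed more than 2-fold, 243 higher and 315 lower. DESeq2 called 2205. Leaving out parental DMSO replicate 1, DMSO replicate 2 or CHIR99021 replicate 1 gave 2087, 2249 and 2057.

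The second comparison asked what CHIR99021 does without β-catenin. The knock-out responded less: T and Sp5 were near 0 and Axin2 fell from 5.01 ± 0.24 to 2.85 ± 0.041 CPM (SD, n = 2 each), a log2 fold change of -0.81 ± 0.12 (adjusted p = 0.00312), opposite to its rise in parental cells. T and Sp5, with log2 fold changes of -1.55 ± 0.61 and -1.66 ± 0.62 (adjusted p = 0.152 and 0.202), were at 0.108 ± 0.0983 and 0.0564 ± 0.0295 CPM with CHIR99021 (SD, n = 2 each). Cdx1 rose from 1.37 ± 0.601 to 3.61 ± 0.0304 CPM (SD, n = 2 each), a log2 fold change of 1.41 ± 0.20 (adjusted p = 0.00247).

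Among the genes with at least 5 CPM in the higher group that rose in the knock-out, the highest fold changes were those of Trpm1 at 1.24 ± 0.11, Cbr3, a carbonyl reductase, at 1.17 ± 0.10, Anxa5 at 1.06 ± 0.11, Patl2 at 0.96 ± 0.14, Wls at 0.92 ± 0.10, B2m at 0.90 ± 0.08, Scara5 at 0.85 ± 0.15 and Gng12 at 0.83 ± 0.13. The annotated span of Patl2 holds B2m on the other strand, so these values may not be separate. At the other end stood Ccnd2, which went from 14.3 ± 0.191 to 4.13 ± 0.00849 CPM (SD, n = 2 each), a log2 fold change of -1.79 ± 0.10. After it came Slc27a2 at -1.28 ± 0.16, the secreted Wnt inhibitor Notum at -1.28 ± 0.12, Adnp at -1.23 ± 0.29, Grhl2 at -1.13 ± 0.14, Crmp1 at -1.09 ± 0.09, Crocc2 at -1.07 ± 0.09 and Ndrg1 at -1.002 ± 0.17. Adnp did not pass with DESeq2 (adjusted p = 0.0747) or without knock-out DMSO replicate 1 (0.123), DMSO replicate 2 (0.0913) or CHIR99021 replicate 2 (0.197). Scara5 did not pass without knock-out DMSO replicate 1 (0.0563) or CHIR99021 replicate 1 (0.0647), nor Ndrg1 without the latter (0.0699). Jup, which encodes plakoglobin, a relative of β-catenin, fell by 0.35 on the log2 scale and Tcf7l1 by 0.41, the latter not without knock-out CHIR99021 replicate 2 (adjusted p = 0.0553).

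Passing no test in the knock-out were Tcf7 at -0.21 ± 0.06, Tcf7l2 at -0.23 ± 0.08, Nanog at -0.11 ± 0.04, Sox2 at -0.12 ± 0.04, Klf4 at -0.07 ± 0.04, Gsk3b at 0.08 ± 0.05 and Lef1 at 0.16 ± 0.56 (adjusted p 0.0718 to 0.905). Gsk3a at -0.01 ± 0.05 and Esrrb at 0.00 ± 0.04 passed none either (adjusted p = 0.958 and 0.967). Nanog passed without knock-out DMSO replicate 2 (adjusted p = 0.0488). Pou5f1, at -0.13 ± 0.04 (adjusted p = 0.0691), passed with DESeq2 (0.0193), limma-voom (0.0459), no filter (0.00559) and without knock-out DMSO replicate 2 (0.0334).

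Gene lists moved in the knock-out as well. Of the 20 Wnt/β-catenin targets 5 fell and 2 rose (adjusted over the list alone 6 and 2; adjusted p = 3.94e-05, and adjusted p = 0.0955 with an estimated correlation), among those that fell Myc at -0.97 ± 0.07 and Ccnd1 at -0.38 ± 0.04. In the LIF/STAT3 response 8 of 16 fell and none rose (adjusted over the list alone 8 fell and 1 rose; adjusted p = 3.42e-08, and adjusted p = 0.0993 with an estimated correlation). The receptor gene Lifr was at -0.41 ± 0.05, Gbx2 at -0.56 ± 0.07 and Pim1 at -0.34 ± 0.04. Adjusted p was 0.123 for this list in parental cells, where 8 fell and 3 rose, also adjusted over the list alone. Of 16 general pluripotency genes 8 fell and none rose (adjusted over the list alone, 14 fell; adjusted p = 3.29e-09, and adjusted p = 0.0955 with an estimated correlation), Trim28 among them at -0.33 ± 0.04. Naive genes gave 7 lower and 1 higher of 22 (adjusted over the list alone 10 and 5; adjusted p = 0.0106, and adjusted p = 0.259 with an estimated correlation). Formative and primed genes gave 4 lower of 17 (adjusted over the list alone, 7; adjusted p = 3.29e-05, and adjusted p = 0.103 with an estimated correlation). Dnmt3a was at -0.32 ± 0.05.

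Signalling lists moved with them. In the FGF/ERK response 5 of 19 fell (adjusted over the list alone, 6; adjusted p = 0.000288, and adjusted p = 0.0993 with an estimated correlation) and in the Nodal/Activin response 3 of 12 (adjusted over the list alone, 6; adjusted p = 0.00349, and adjusted p = 0.103 with an estimated correlation). The streak list was lower with 1 gene called of 15, Fgf17 at -0.63 ± 0.07, also adjusted over the list alone (adjusted p = 0.0107, and adjusted p = 0.124 with an estimated correlation; 0.0556 without knock-out CHIR99021 replicate 2). Definitive endoderm (1 higher and 3 lower of 9, also adjusted over the list alone; adjusted p = 0.0391, and adjusted p = 0.2 with an estimated correlation) and neural ectoderm (1 higher and 5 lower of 12, also adjusted over the list alone; adjusted p = 0.0323, and adjusted p = 0.2 with an estimated correlation) did not pass in most refits with 1 library left out. Definitive endoderm passed without knock-out CHIR99021 replicate 1 alone and was at 0.0857 to 0.244 otherwise. Neural ectoderm passed without parental CHIR99021 replicate 1 or knock-out DMSO replicate 2 and was at 0.0613 to 0.113 otherwise.

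Lysosome genes rose in the knock-out too, with 9 of 30 higher and 3 lower (adjusted over the list alone 16 and 4; adjusted p = 3.42e-08, and adjusted p = 0.0955 with an estimated correlation). Ctsl was at 0.63 ± 0.04, Hexa at 0.57 ± 0.07 and Ctsb at 0.39 ± 0.05. The NRF2 response, a set of antioxidant genes, gave 5 higher and 1 lower of 16 (adjusted over the list alone 7 and 2; adjusted p = 0.00044, and adjusted p = 0.103 with an estimated correlation). Nqo1 was at 0.58 ± 0.05, Me1 at 0.59 ± 0.09 and Srxn1 at 0.41 ± 0.05. The p53 response gave 7 higher and 1 lower of 20 (adjusted over the list alone 9 and 1; adjusted p = 0.000277, and adjusted p = 0.103 with an estimated correlation). Among them were Ccng1 at 0.42 ± 0.06 and Mdm2 at 0.39 ± 0.06. Among DNA replication genes 6 of 25 fell and 1 rose (adjusted over the list alone 12 and 1; adjusted p = 2.35e-05, and adjusted p = 0.218 with an estimated correlation), and among G2/M genes 7 of 22 fell (adjusted over the list alone 13 fell and 1 rose; adjusted p = 6.71e-07, and adjusted p = 0.103 with an estimated correlation). Ccne1, which encodes cyclin E1, was at -0.40 ± 0.04, Mcm6 at -0.28 ± 0.04 and Cdc20 at -0.33 ± 0.04. Sterol synthesis went lower, against its direction in parental cells, with 3 of 24 called (adjusted over the list alone, 6; adjusted p = 0.00184, and adjusted p = 0.259 with an estimated correlation). Glycolysis and hypoxia genes gave 6 lower and 1 higher of 29 (adjusted over the list alone 10 and 2; adjusted p = 0.0204, and adjusted p = 0.352 with an estimated correlation), the glucose transporter gene Slc2a1 at -0.33 ± 0.04. This list did not pass without knock-out DMSO replicate 2 (0.0621) or CHIR99021 replicate 2 (0.0578).

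In all, 1252 genes changed in the knock-out, 510 higher and 742 lower, of which 50 changed more than 2-fold, 19 higher and 31 lower. The count was 335 without knock-out DMSO replicate 1, 307 without CHIR99021 replicate 1, 328 without CHIR99021 replicate 2 and 2167 with no filter on low counts.

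The interaction tested whether the response itself differed between the lines; its values are the response of the knock-out minus that of parental cells. It differed for 1087 genes, 571 with a higher and 516 with a lower value, and 240 by more than 2-fold. Of these genes 964 were called in parental cells, and 949 of the 964 had a smaller response in the knock-out. Both calls use the same parental libraries, so this choice of genes itself favours a smaller response in the knock-out. Among the most negative values were those of Sp5 at -8.12 ± 0.78, T at -6.60 ± 0.70, Nkx1-2 at -6.22 ± 1.24, Dmgdh at -5.25 ± 0.95, Eomes at -4.74 ± 0.21, Cdx1 at -4.44 ± 0.29, Axin2 at -4.11 ± 0.15 and Calb2, which encodes calretinin, at -3.60 ± 0.50. In the knock-out with CHIR99021, Sp5, T and Nkx1-2 had only 3, 6 and 3 counts, so the size of their values is poorly determined. Dmgdh and Calb2 were low in the knock-out too, at group means of 0.207 to 0.388 CPM. Nkx1-2 did not pass without knock-out DMSO replicate 1 (adjusted p = 0.137), nor Dmgdh without DMSO replicate 2 (0.118). Among the most positive, of genes that CHIR99021 lowered in parental cells, were Enpp3 at 3.02 ± 0.18, Bcl11a at 2.60 ± 0.37, Hhip at 2.40 ± 0.26, Pirt at 2.06 ± 0.38, Id2 at 1.97 ± 0.14, Tgfbi at 1.94 ± 0.09, Slc27a2 at 1.93 ± 0.28 and Zfp521 at 1.75 ± 0.21.

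Among the genes fixed in advance, Tcf7 at -0.93 ± 0.09, Tcf7l1 at 0.66 ± 0.09, Klf4 at -0.32 ± 0.06, Jup at -0.33 ± 0.07 and Sox2 at 0.26 ± 0.06 had responses that differed. Jup did not pass without parental DMSO replicate 1 (0.0536), CHIR99021 replicate 1 (0.0634) or knock-out CHIR99021 replicate 2 (0.0752). Sox2 did not pass without parental DMSO replicate 1 (0.105), CHIR99021 replicates 1 (0.0637) or 2 (0.0788), or knock-out DMSO replicate 1 (0.0813), CHIR99021 replicate 1 (0.0893) or 2 (0.0761). No difference passed for Ctnnb1 at 0.07, Gsk3a at -0.03, Gsk3b at 0.13, Tcf7l2 at 0.23, Lef1 at 0.18, Nanog at 0.08, Esrrb at 0.00 or Pou5f1 at 0.00 (SE 0.05 to 0.80; adjusted p 0.309 to 0.998).

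By list, 11 of 20 Wnt/β-catenin targets had a lower value (adjusted over the list alone, 12; adjusted p = 2.24e-19, and adjusted p = 0.0179 with an estimated correlation), and so had 3 of 15 streak genes (adjusted over the list alone, 5; adjusted p = 1.31e-05, and adjusted p = 0.0765 with an estimated correlation). Trophoblast genes gave 4 lower of 14, also adjusted over the list alone (adjusted p = 0.00231, and adjusted p = 0.115 with an estimated correlation). For sterol synthesis 7 of 24 were lower (adjusted over the list alone, 21; adjusted p = 5.82e-13, and adjusted p = 0.0982 with an estimated correlation). Ebp was at -0.88 ± 0.11 and Fdft1 at -0.52 ± 0.06. In DNA replication 3 of 25 were lower (adjusted over the list alone, 6; adjusted p = 0.00113, and adjusted p = 0.44 with an estimated correlation). Values were higher for 8 of 16 general pluripotency genes (adjusted over the list alone 12 higher and 1 lower; adjusted p = 2.55e-08, and adjusted p = 0.0765 with an estimated correlation), such as Sall1 at 0.40 ± 0.05 and L1td1 at 0.38 ± 0.05. They were higher for 5 and lower for 1 of 17 formative genes (adjusted over the list alone 6 and 1; adjusted p = 0.000949, and adjusted p = 0.175 with an estimated correlation). Dnmt3a was at 0.73 ± 0.07. Nodal/Activin genes gave 5 higher of 12 (adjusted over the list alone 6 higher and 2 lower; adjusted p = 1.31e-05, and adjusted p = 0.0765 with an estimated correlation). Lefty1 was at 1.74 ± 0.11. Neural ectoderm gave 6 higher of 12 (adjusted over the list alone 6 higher and 1 lower; adjusted p = 0.000179, and adjusted p = 0.0982 with an estimated correlation). Tubb3 was at 0.78 ± 0.09. The same direction held for extraembryonic endoderm with 6 higher and 1 lower of 23 (adjusted over the list alone 8 and 2; adjusted p = 4e-05, and adjusted p = 0.16 with an estimated correlation). Lrp2 was at 1.62 ± 0.09. It held for basement membrane with 8 higher and 2 lower of 21 (adjusted over the list alone 10 and 2; adjusted p = 0.000179, and adjusted p = 0.289 with an estimated correlation). Col4a1 was at 1.06 ± 0.11. The count of 1087 was 700 without parental DMSO replicate 1, 628 without CHIR99021 replicate 1, 691 without knock-out DMSO replicate 1, 605 without CHIR99021 replicate 2 and 1990 with no filter on low counts.

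Part of the response was shared. For 77.9% of the 3441 genes called in parental cells the log2 fold change in the knock-out had the same sign, whether or not it passed the test, where unrelated signs would give 50.3%. Both lines called 723 genes. Of these, 258 rose in both and 425 fell in both, where independent calls would give 46.4 and 76.4, and 40 changed in opposite directions. The expected numbers take each gene as equally likely to be called. Genes with more counts are called more readily, so the excess may be overstated. Among the genes called with the same sign, 516 showed no call in the interaction. Across the 3441 genes the median ratio of the knock-out's log2 fold change to the parental one was 0.284, and it was 0.193 over the 558 genes with more than a 2-fold change. Both sets were picked on the parental response, which tends to make these ratios smaller. The Spearman correlation across all genes of both responses, which share no library, was 0.285 and the Pearson correlation 0.0803; genes are not independent replicates, so no p is given. Over the genes called in parental cells they were 0.574 and 0.271. The Pearson value was 0.00906 and 0.0372 without replicate 2 of parental DMSO or CHIR99021, 0.0301 without knock-out DMSO replicate 2 and 0.0281 without knock-out CHIR99021 replicate 1. In simulated counts with no change in either line the Spearman correlation was 0.021. Those counts were drawn independently for each gene and library, so they cannot show what effects shared by libraries, such as a batch, would give. Mitochondrial genes took a higher share of counts with CHIR99021 in both lines, 3.66% and 3.74% against 3.31% and 3.43% in parental cells and 3.87% and 4.11% against 3.18% and 3.49% in the knock-out.

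**Figure D2:**
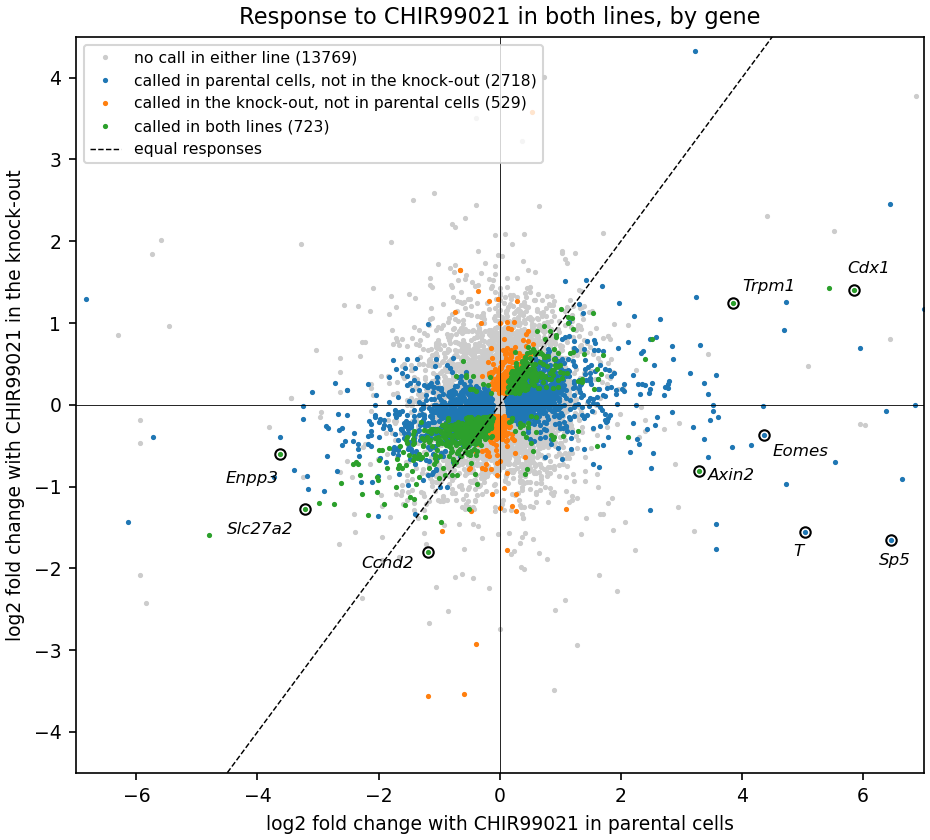
Log2 fold change with CHIR99021 of each gene in parental cells (horizontal) and in the knock-out (vertical), coloured by call; the dashed line marks equal responses, and 55 genes lie outside the axes. Of 723 genes called in both lines 683 lie in the quadrants of equal sign, while T, Sp5, Axin2 and Eomes lie far to the right near or below 0 on the vertical axis.

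The third comparison set the knock-out against parental cells in DMSO, that is, without the inhibitor. Its differences may come from loss of β-catenin or from other differences between the lines. Apart from Ctnnb1, at -6.59 ± 0.09 on the log2 scale (adjusted p = 7.48e-12), few genes differed by much, 79 of the 1198 called by more than 2-fold. Axin2 at 0.23 ± 0.11, Cdx1 at -0.42 ± 0.23, Sp5 at 1.48 ± 0.62 and T at -0.01 ± 0.49 passed no test (adjusted p 0.298 to 0.992), at levels of 0.0637 to 5.01 CPM. Of the basement membrane list 9 of 21 genes, and of the extraembryonic endoderm list 9 of 23, were higher in the knock-out and 1 of each lower (adjusted p = 0.146 and adjusted p = 0.111 with an estimated correlation). Col4a1 (ENSMUSG00000031502, chromosome 8, 11198423 to 11312826) went from 32.0 ± 2.06 to 73.8 ± 3.94 CPM (SD, n = 2 each) and its neighbour Col4a2 from 13.7 ± 0.0636 to 30.5 ± 1.2 CPM (SD, n = 2 each), log2 fold changes of 1.21 ± 0.07 and 1.15 ± 0.07. Nrxn3, a neurexin (ENSMUSG00000066392, chromosome 12, 88722876 to 90334935), was almost missing from the knock-out, with 4 counts against 434 in DMSO, a ratio of 123 (47.8 to 454), and 2 against 484 in CHIR99021, a ratio of 262 (72 to 2170).

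Other genes among those with the highest fold changes were the Y-linked helicase gene Ddx3y at 1.70 ± 0.09, the endocytic adaptor Dab2 at 1.35 ± 0.16, Dnmt3l, a cofactor of DNA methyltransferases, at 1.16 ± 0.05, Sfmbt2 at 1.15 ± 0.06 and Mrpl23 at 1.14 ± 0.30. Among the lowest were Nudt12 at -1.24 ± 0.16, Igf2bp3 at -1.14 ± 0.06, Pttg1, which encodes securin, at -1.06 ± 0.07, Islr2 at -1.06 ± 0.11, D2hgdh at -0.998 ± 0.11 and Pirt at -0.94 ± 0.25. Mrpl23, whose adjusted p rounds to 0.05, passed in none of DESeq2 (0.111), limma-voom (0.0848) and the refits without parental DMSO replicates 1 (0.187) and 2 (0.194), parental CHIR99021 replicates 1 (0.0633) and 2 (0.064) or knock-out DMSO replicates 1 (0.23) and 2 (0.0955). Pirt failed with DESeq2 (0.0866) and without the same 6 libraries (0.139, 0.192, 0.0575, 0.0584, 0.236 and 0.0837 in that order).

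Of the 23 measured genes of primitive and extraembryonic endoderm (31 listed) 9 were higher and 1 lower in the knock-out (adjusted over the list alone 11 and 1; adjusted p = 7.6e-13, and adjusted p = 0.111 with an estimated correlation). The transcription factor gene Gata4 was at 1.08 ± 0.14 and Lrp2 at 0.60 ± 0.06. Basement membrane genes gave 9 higher and 1 lower of 21 (adjusted over the list alone 10 and 1; adjusted p = 6.22e-12, and adjusted p = 0.146 with an estimated correlation). Lama5 was at 0.37 ± 0.04 and Col18a1 at 0.33 ± 0.04. Naive pluripotency genes were lower, 7 of 22 against 1 higher (adjusted over the list alone 9 and 1; adjusted p = 0.000177, and adjusted p = 0.195 with an estimated correlation): Tdh at -0.36 ± 0.04, Manba at -0.34 ± 0.04 and Nanog at -0.20 ± 0.04. Nanog, from 617.5 ± 2.97 to 537.6 ± 15.6 CPM (SD, n = 2 each), did not pass without parental DMSO replicate 1 (adjusted p = 0.0754) or 2 (0.0555). Klf4, at -0.16 ± 0.04 (adjusted p = 0.0374), passed in no refit without 1 library (adjusted p 0.0554 without parental CHIR99021 replicate 2 to 0.283 without parental DMSO replicate 1), nor with the compared groups alone (0.0909). Of general pluripotency genes 2 of 16 were higher, also adjusted over the list alone (adjusted p = 0.000634, and adjusted p = 0.195 with an estimated correlation).

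No difference passed for Pou5f1 at -0.05, Sox2 at -0.12, Esrrb at -0.12, Gsk3a at 0.06, Gsk3b at -0.10, Jup at 0.00, Tcf7 at 0.02, Tcf7l1 at 0.15, Tcf7l2 at 0.17 or Lef1 at -0.08 (SE 0.04 to 0.57; adjusted p 0.106 to 0.993). Esrrb passed with no filter on low counts (0.0261) and without knock-out DMSO replicate 1 (0.0405).

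The p53 response was higher in 6 of 20 (adjusted over the list alone, 11; adjusted p = 1.12e-07, and adjusted p = 0.111 with an estimated correlation). Plk2 was at 0.53 ± 0.08 and Phlda3 at 0.36 ± 0.05. Senescence and cell-cycle inhibitor genes gave 2 higher of 11 (adjusted over the list alone, 3; adjusted p = 0.00652, and adjusted p = 0.181 with an estimated correlation), with Cdkn1c, which encodes p57, at 0.51 ± 0.06. The unfolded protein and integrated stress response was lower in 6 of 22 and higher in 1 (adjusted over the list alone 8 and 1; adjusted p = 5.17e-05, and adjusted p = 0.17 with an estimated correlation). Chac1 was at -0.81 ± 0.09, Trib3 at -0.37 ± 0.06 and Asns at -0.27 ± 0.04. DNA replication genes were lower in 5 of 25 (adjusted over the list alone, 6; adjusted p = 5.17e-05, and adjusted p = 0.271 with an estimated correlation). Pcna was at -0.35 ± 0.04 and Gins1 at -0.31 ± 0.05. G2/M genes were lower in 7 of 22 (adjusted over the list alone 9 lower and 1 higher; adjusted p = 5.17e-05, and adjusted p = 0.195 with an estimated correlation). Bub1 was at -0.45 ± 0.04, Nusap1 at -0.34 ± 0.04 and Bub1b at -0.25 ± 0.04. Of the 7 lower G2/M genes 6, Bub1, Nusap1 and Bub1b among them, lie on distal chromosome 2, where genes were lower as a block. So do 2 of the 5 lower replication genes, Pcna and Gins1, and 2 of the 6 lower stress response genes, Chac1 and Trib3. Without the genes of distal chromosomes 1 and 2, an alternative chosen after seeing the data, the G2/M list had adjusted p = 0.176, and DNA replication and the stress response 0.000833 each. Of 6 measured Y-linked genes (8 listed) 4 were higher, also adjusted over the list alone (adjusted p = 3.84e-20, and adjusted p = 0.111 with an estimated correlation): Ddx3y, Uba1y at 0.88 ± 0.12, Uty at 0.77 ± 0.06 and Eif2s3y at 0.43 ± 0.04.

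Weaker calls were for sterol synthesis (4 of 24 lower; adjusted over the list alone 7 lower and 1 higher; adjusted p = 0.026, and adjusted p = 0.452 with an estimated correlation), not past the threshold without parental DMSO replicate 1 (0.163) or knock-out DMSO replicate 2 (0.192). The lysosome list (5 lower and 2 higher of 30; adjusted over the list alone 6 and 2; adjusted p = 0.0401, and adjusted p = 0.195 with an estimated correlation) failed without parental DMSO replicate 2 (0.0714), knock-out DMSO replicate 2 (0.0797) or the distal genes of chromosomes 1 and 2 (0.0865). The Notch response (2 of 10 higher, also adjusted over the list alone, Notch3 at 0.60 ± 0.07; adjusted p = 0.0443, and adjusted p = 0.211 with an estimated correlation) failed without parental DMSO replicate 1 (0.076) or knock-out DMSO replicate 2 (0.0826).

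At the threshold 1198 genes differed in DMSO, 556 higher and 642 lower in the knock-out, and of the 79 with more than a 2-fold difference 53 were higher and 26 lower. The count was 774 without the genes of distal chromosomes 1 and 2, 795 with DESeq2 and 2064 with no filter on low counts. It was 357 and 510 without parental DMSO replicates 1 and 2, and 561 and 717 without knock-out DMSO replicates 1 and 2.

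Part of the difference between the lines followed chromosome position. For each chromosome but Y, the position was chosen that best split the log2 fold changes in DMSO. Genes with a mean of at least 2 CPM were used, with at least 30 on each side. The DMSO values of the segments thus come from the data that chose them. The median log2 fold change of genes beyond position 93955810 on chromosome 2 (582 genes with enough counts) was -0.207 in DMSO and -0.205 in CHIR99021, against -0.013 and -0.025 for the 421 genes before it. In DMSO 85.7% of the distal genes were lower. Beyond position 163929100 on chromosome 1 the medians of 178 genes were 0.167 and 0.176, against 0.011 and 0.028 for 596 genes before it. In the 8 pairs of single knock-out and parental libraries of the same treatment the distal chromosome 2 median lay between -0.228 and -0.193. Distal chromosome 2 held 241 of the 1198 calls in DMSO, 236 of them lower. These calls are among all 782 genes tested there, with no floor on CPM. Over all genes tested 6.75% were called in DMSO.

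**Figure D3:**
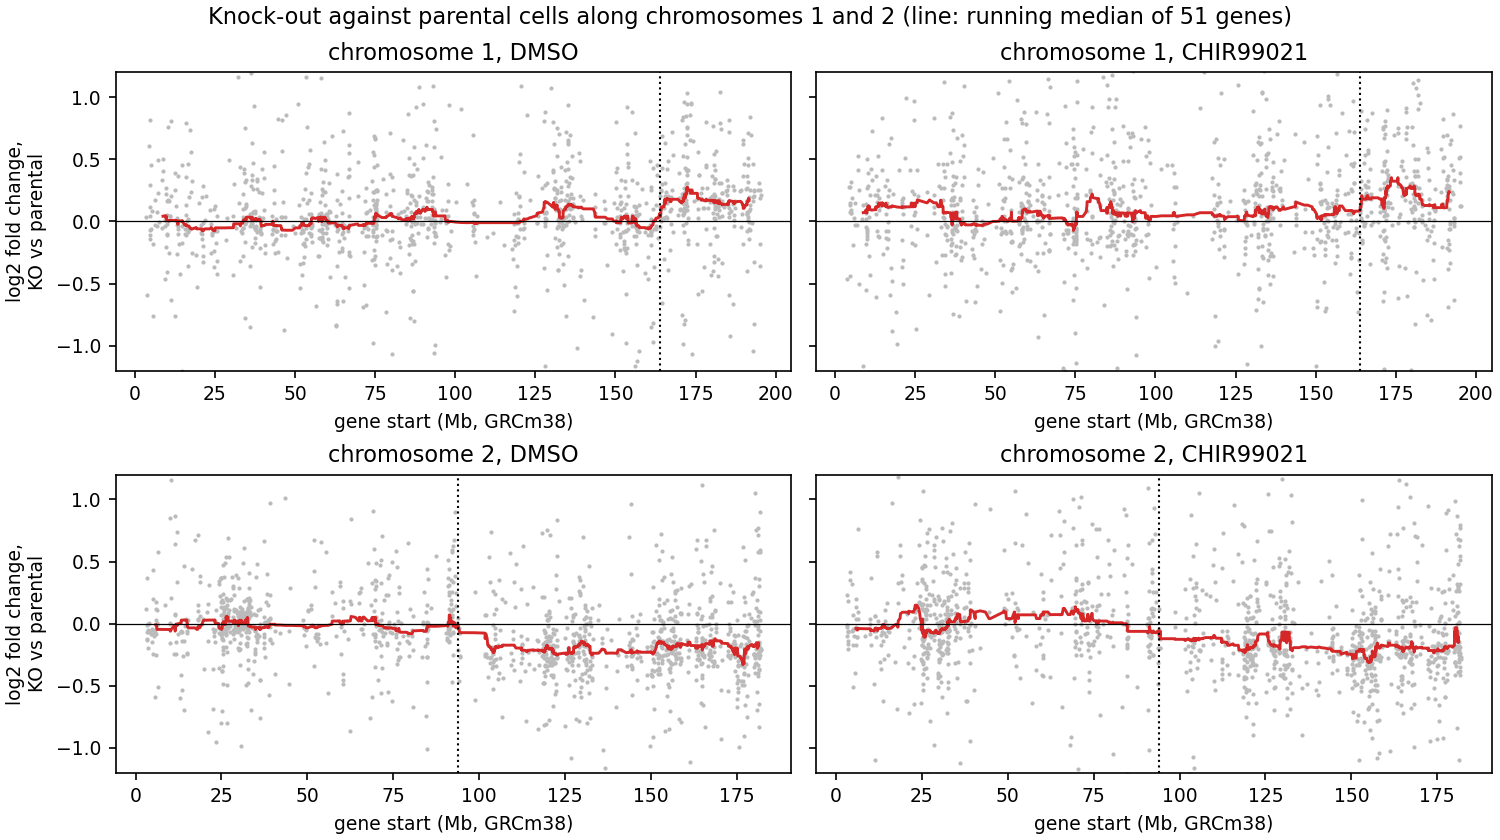
Log2 fold change of knock-out against parental cells for each gene tested on chromosomes 1 and 2 by gene start (grey points, drawn between -1.2 and 1.2), with the running median of 51 genes in red and the start of the shifted part dotted, in DMSO and CHIR99021. The median is -0.207 in DMSO beyond the dotted line on chromosome 2 and 0.167 beyond that on chromosome 1.

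The fourth comparison set the knock-out against parental cells in CHIR99021. Several targets that rose in parental cells were lower in the knock-out, among them Axin2 at -3.88 ± 0.10, Cdx1 at -4.86 ± 0.11, Eomes at -4.82 ± 0.12 and Tcf7 at -0.92 ± 0.06 on the log2 scale. For genes with few counts the ratio of parental to knock-out cells was 108 (36.6 to 527) for Sp5 and 197 (67.1 to 958) for Nkx1-2. Their fitted log2 fold changes were -6.63 and -7.50, and that of T, with 6 counts in the knock-out, was -6.61 ± 0.37. Nrxn3 and Ctnnb1 were lower as well, at -7.85 and -6.51. Higher in the knock-out were Enpp3 at 3.38 ± 0.14, Khdc3 at 2.47 ± 0.18, AU015836 at 2.28 ± 0.09, Col4a1 at 2.26 ± 0.08 and Lrp2 at 2.23 ± 0.07. Tcf7l1 was higher by 0.81 ± 0.07 and Klf4 and Jup lower, at -0.48 ± 0.04 and -0.33 ± 0.05.

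Differences near the threshold were those of Tcf7l2 at 0.41 ± 0.09, Sox2 at 0.14 ± 0.04 (adjusted p = 0.0295) and Nanog at -0.12 ± 0.04 (adjusted p = 0.0288). Tcf7l2 did not pass without parental CHIR99021 replicate 1 (0.0645) or knock-out CHIR99021 replicate 1 (0.0588). Sox2 did not pass without any 1 of parental CHIR99021 replicates 1 (0.0818) and 2 (0.141) and knock-out CHIR99021 replicates 1 (0.145) and 2 (0.0963). Nanog failed without these (0.0897, 0.103, 0.154 and 0.0948 in that order) and without parental DMSO replicates 1 (0.061) and 2 (0.0552). Esrrb, at -0.11 ± 0.04 (adjusted p = 0.0538), passed with DESeq2 (0.0326), limma-voom (0.0398), no filter (0.0234) and without knock-out DMSO replicates 1 (0.0181) or 2 (0.0163). Pou5f1 at -0.05, Gsk3a at 0.02, Gsk3b at 0.04 and Lef1 at 0.10 passed no test (SE 0.04 to 0.56; adjusted p 0.406 to 0.925).

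Of 20 Wnt/β-catenin targets 11 were lower in the knock-out and none higher (adjusted over the list alone, 13; adjusted p = 6.7e-23, and adjusted p = 0.0129 with an estimated correlation). Streak genes gave 5 lower of 15, also adjusted over the list alone (adjusted p = 3.96e-07, and adjusted p = 0.0482 with an estimated correlation), and trophoblast genes 4 lower and 2 higher of 14, also adjusted over the list alone (adjusted p = 0.00576, and adjusted p = 0.115 with an estimated correlation). In sterol synthesis 20 of 24 were lower and none higher, also adjusted over the list alone (adjusted p = 7.46e-15, and adjusted p = 0.0628 with an estimated correlation). Ebp was at -1.21 ± 0.07, Fdft1 at -0.58 ± 0.04 and Insig1 at -0.63 ± 0.06. General pluripotency genes were higher in 13 of 16, also adjusted over the list alone (adjusted p = 1.96e-12, and adjusted p = 0.0482 with an estimated correlation). Dnmt3l was at 1.58 ± 0.05, Dppa2 at 0.51 ± 0.04 and Sall1 at 0.35 ± 0.03. The naive list gave 8 lower and 5 higher of 22 (adjusted over the list alone 10 and 5; adjusted p = 0.0421, and adjusted p = 0.33 with an estimated correlation): Tdh at -1.11 ± 0.04 and Tfcp2l1 at -0.76 ± 0.03 against Fgf4 at 0.81 ± 0.04 and Tcl1 at 0.62 ± 0.04. It did not pass without parental CHIR99021 replicate 2 (0.069) or knock-out CHIR99021 replicates 1 (0.0614) or 2 (0.063).

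Formative genes gave 8 higher and 1 lower of 17 (adjusted over the list alone 10 and 2; adjusted p = 0.000821, and adjusted p = 0.134 with an estimated correlation). Dnmt3a was at 1.26 ± 0.05. Extraembryonic endoderm gave 12 higher and 3 lower of 23 (adjusted over the list alone 15 and 3; adjusted p = 9.91e-14, and adjusted p = 0.0491 with an estimated correlation), and basement membrane 13 higher and 2 lower of 21 (adjusted over the list alone 14 and 2; adjusted p = 2.23e-13, and adjusted p = 0.0628 with an estimated correlation). Col4a2 was at 2.05 ± 0.07. Neural ectoderm gave 6 higher and 1 lower of 12 (adjusted over the list alone 7 and 3; adjusted p = 0.0141, and adjusted p = 0.141 with an estimated correlation). Tubb3 was at 0.86 ± 0.06 and Map2 at 0.87 ± 0.11. The Nodal/Activin response gave 8 higher and 2 lower of 12, also adjusted over the list alone (adjusted p = 9.06e-07, and adjusted p = 0.0482 with an estimated correlation). Of its members 3, Lefty1 among them, lie on distal chromosome 1, where genes were higher as a block, and without the distal genes of both chromosomes it gave 5 higher and 2 lower of 9 (adjusted p = 0.0082). Lefty1 was at 2.08 ± 0.08 and Skil at 1.05 ± 0.05. The Notch response gave 3 higher and 1 lower of 10 (adjusted over the list alone 4 and 1; adjusted p = 0.0127, and adjusted p = 0.134 with an estimated correlation).

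DNA replication genes were lower in 18 of 25 (adjusted over the list alone, 19, with adjusted p = 6.37e-08, and adjusted p = 0.141 with an estimated correlation). Of these 2 lie on distal chromosome 2, among them Pcna at -0.47 ± 0.04. G2/M genes were lower in 10 of 22 and higher in 1 (adjusted over the list alone 11 and 2; adjusted p = 0.00786, and adjusted p = 0.281 with an estimated correlation). Ube2c was at -0.45 ± 0.06 and Aurka at -0.33 ± 0.04. Of the 10 lower genes 6, Ube2c and Aurka among them, lie on distal chromosome 2, and without the distal genes of both chromosomes this list had adjusted p = 0.147. The p53 response gave 9 higher and 1 lower of 20 (adjusted over the list alone 13 and 1; adjusted p = 0.0312, and adjusted p = 0.26 with an estimated correlation; 0.0701 without parental CHIR99021 replicate 2), the lower one being Cdkn1a at -1.15 ± 0.06. The LIF/STAT3 response (5 lower and 4 higher of 16, also adjusted over the list alone, Pim1 at -1.1 ± 0.04; adjusted p = 0.0455, and adjusted p = 0.316 with an estimated correlation) failed without parental DMSO replicates 1 (0.0511) or 2 (0.0533), parental CHIR99021 replicate 1 (0.0803), or knock-out CHIR99021 replicates 1 (0.0614) or 2 (0.111), and with a replicate block (0.0616). Y-linked genes gave 5 higher of 6, also adjusted over the list alone (adjusted p = 2.96e-11, and adjusted p = 0.0628 with an estimated correlation). Ddx3y was at 1.77 ± 0.09.

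In CHIR99021, 4200 genes differed, 1990 higher and 2210 lower in the knock-out, of which 592 differed more than 2-fold, 366 higher and 226 lower. DESeq2 called 2709, and the count was 2586, 2678 and 2509 without parental CHIR99021 replicate 1, knock-out CHIR99021 replicate 1 or replicate 2. Of the genes called in both DMSO and CHIR99021, 372 were higher and 408 lower in the knock-out under both treatments and 30 changed sides, where independent calls would give 62.4 and 80.0. Here, too, the expected numbers take each gene as equally likely to be called, so the excess may be overstated.

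**Figure D4:**
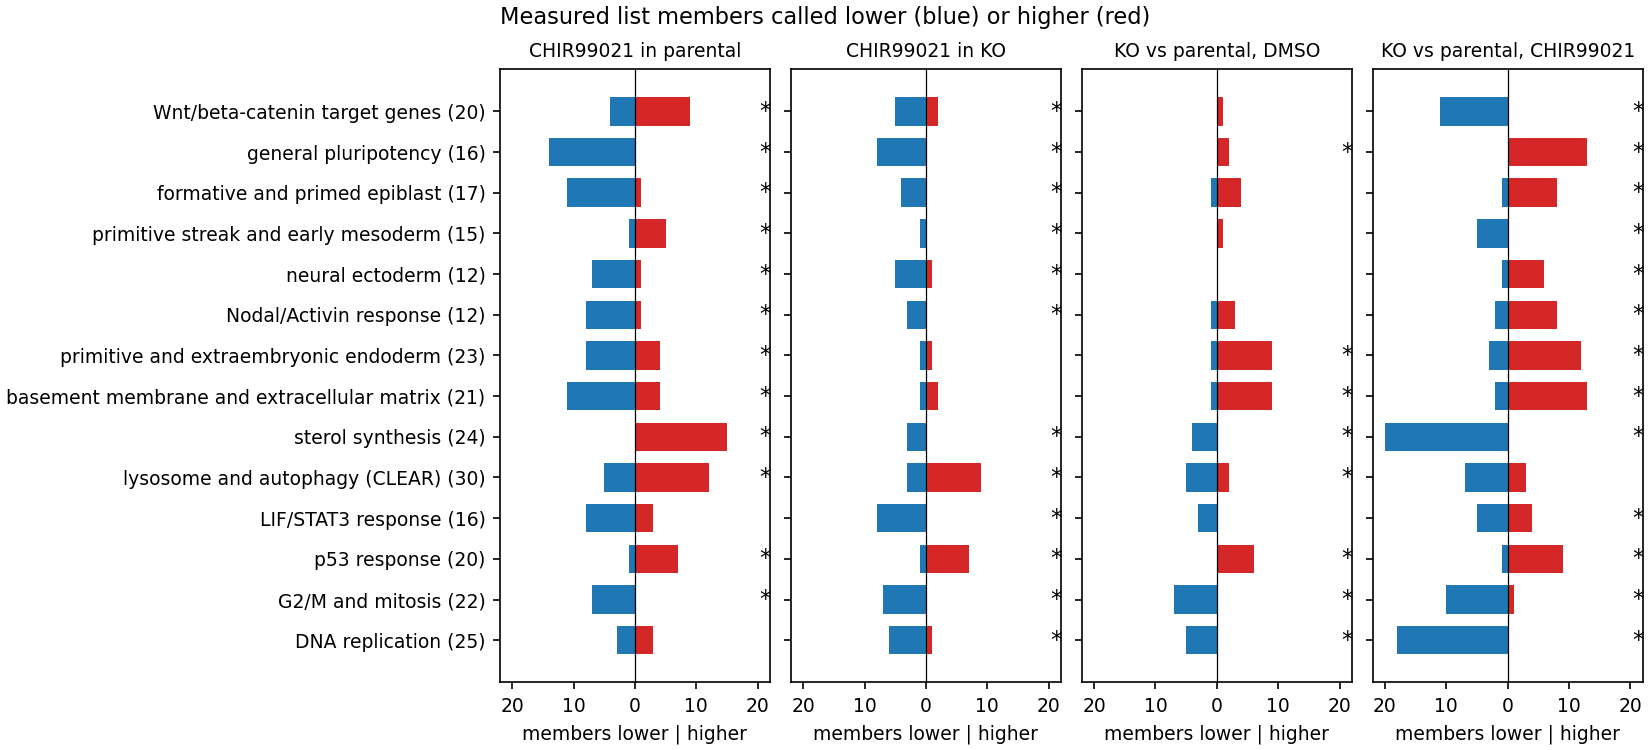
Number of measured members of 14 gene lists (measured number in brackets) called lower, to the left in blue, or higher, to the right in red, in 4 comparisons; an asterisk marks a list test past an adjusted p of 0.05 with the preset correlation. Wnt/β-catenin targets show 9 higher and 4 lower with CHIR99021 in parental cells, 2 and 5 in the knock-out, and 0 and 11 for knock-out against parental cells in CHIR99021.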

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

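Of the tests in this part, the one on mixing of cells or reads and the one on residual β-catenin were chosen only after the result was seen.

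The results below stand out because the response to CHIR99021 differed between parental and knock-out cells by the interaction test, which called 1087 genes. Values are the log2 response of the knock-out minus that of parental cells. Lower values were found for Sp5 (-8.12), T (-6.60), Nkx1-2 (-6.22), Dmgdh (-5.25), Eomes (-4.74), Cdx1 (-4.44), Axin2 (-4.11), Calb2 (-3.60) and Tcf7 (-0.93). Those of Sp5, T and Nkx1-2 rest on 3, 6 and 3 counts in the knock-out with CHIR99021, so their size is poorly determined. Lower, too, were Porcn (-1.61), which encodes the enzyme that lipidates Wnt proteins, Cdkn1a (-1.302), Id3 (-1.28), Ebp (-0.88), Fdft1 (-0.52), Jup (-0.33) and Klf4 (-0.32). Ccnd2 (-0.61) fell in both lines and by more in the knock-out; its difference did not pass with DESeq2 (adjusted p = 0.208) or without parental DMSO replicate 2 (0.0836), parental CHIR99021 replicates 1 (0.108) or 2 (0.0505), knock-out DMSO replicate 1 (0.078), or knock-out CHIR99021 replicates 1 (0.0735) or 2 (0.0879). Without knock-out DMSO replicate 1, Nkx1-2 had adjusted p = 0.137, and without DMSO replicate 2 Dmgdh had 0.118. Jup had 0.0536 without parental DMSO replicate 1, 0.0634 without parental CHIR99021 replicate 1 and 0.0752 without knock-out CHIR99021 replicate 2.

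Higher were Enpp3 (3.02), Bcl11a (2.60), Hhip (2.40), Pirt (2.06), Id2 (1.97), Tgfbi (1.94), Slc27a2 (1.93), Zfp521 (1.75), Lefty1 (1.74), Lrp2 (1.62), Col4a1 (1.06), Cdkn1c (1.04), Fgf4 (0.84), Tubb3 (0.78), Dnmt3a (0.73), Tcf7l1 (0.66), Sall1 (0.40), L1td1 (0.38) and Sox2 (0.26), all of which CHIR99021 lowered in parental cells. Sox2 lost its call without any 1 of 6 libraries, with adjusted p = 0.105 and 0.0637 without replicate 1 of parental DMSO and CHIR99021, 0.0788 without parental CHIR99021 replicate 2, 0.0813 without knock-out DMSO replicate 1, and 0.0893 and 0.0761 without knock-out CHIR99021 replicates 1 and 2. By list, the response differed for Wnt/β-catenin targets (adjusted p = 2.24e-19), sterol synthesis (5.82e-13), general pluripotency (2.55e-08), the primitive streak (1.31e-05), the Nodal/Activin response (1.31e-05), extraembryonic endoderm (4e-05), neural ectoderm (0.000179), basement membrane (0.000179), formative and primed epiblast (0.000949), DNA replication (0.00113) and trophoblast (0.00231). These are from camera with the preset correlation. Wnt/β-catenin targets had adjusted p = 0.0179 with an estimated correlation, and the other 10 lists did not pass with it (adjusted p 0.0765 to 0.44). That setting also uses fewer degrees of freedom, so the lost calls do not measure correlation between genes alone.

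Besides these differences, both lines shared part of the response, with 683 genes called in both and changed the same way. A trend on GC content, transcript length or expression level as the whole cause is argued against by the Spearman correlation of both responses, which was 0.284 before and 0.307 after such trends were removed from 17680 genes. Parental cells or reads mixed into the knock-out libraries are argued against by the size of the change: over 1827 genes lower in parental cells the median change in CPM in the knock-out was 0.366 of the parental one, while Ctnnb1 was at about 1.04% of its parental level. Activity of residual β-catenin as the whole cause is argued against by Axin2, which moved by -0.815 in the knock-out, and by Wnt/β-catenin targets, of which 5 of 20 fell there and 2 rose, though Cdx1 rose by 1.41 and the truncated or residual product itself was not measured. What may remain is an action of CHIR99021 that does not need β-catenin, or a batch shared by the treated libraries, which the labels neither give nor rule out.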

How the results depend on the processing

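The alternative without the genes of distal chromosomes 1 and 2 was chosen only after the results were seen; the other alternatives were planned. With 2 libraries per group the counts of called genes depend on single libraries, and the depth keeps small changes in genes under about 1 CPM, such as Lef1, out of reach. Without 1 library in turn the counts ran from 2057 to 3507 for CHIR99021 in parental cells, 307 to 1237 in the knock-out, 357 to 1047 for the knock-out in DMSO, 2509 to 4353 in CHIR99021 and 605 to 1143 for the interaction. DESeq2 called 2205 genes in parental cells, 795 for the knock-out in DMSO and 2709 in CHIR99021. With no filter on low counts 2167 were called for CHIR99021 in the knock-out, 2064 for the knock-out in DMSO and 1990 in the interaction. An adjusted p under 0.01 gave 1897, 342, 411, 2403 and 509 genes in the order of the comparisons, and a fold change over 2 gave 558, 50, 79, 592 and 240, fewer by construction. Without the distal genes of chromosomes 1 and 2, the knock-out differed in 774 of 16685 genes in DMSO, while 911 of the 1198 calls lay outside them, so fewer genes tested account for part of the fall. With the estimated correlation 9 list tests passed. The Spearman correlation of both responses was 0.574 over genes called in parental cells, 0.397 with the stricter filter and 0.217 to 0.267 without 1 library. The median of chromosome 2 in DMSO was -0.109 with the stricter filter against -0.095. Unless the construction shows it, the cause was not tested. Replicate numbers did not pair the libraries, as the deviations of replicates from their group means correlated between groups by -0.056 to 0.104; a replicate block gave 3434, 1313, 1225, 4296 and 1135 genes. With it the Nodal/Activin list gained a call for the knock-out in DMSO (adjusted p = 0.0269; 0.0528 without a block and without the distal genes) and the LIF/STAT3 list lost its call in CHIR99021 (0.0616), where the senescence list gained one without knock-out CHIR99021 replicate 2 (0.0236). Relative log expression factors, limma-voom, the stricter filter and the compared groups alone kept each count within 1.5 times.

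Of 2240 values of named genes without 1 library, 2135 kept direction and side of the threshold, 63 lost and 5 gained a call. Signs turned for 19 values near 0, each uncalled (adjusted p at least 0.333 after the turn). Their ranges without 1 library were as follows. For CHIR99021 in parental cells: Jup -0.052 to 0.007, Lef1 -0.254 to 0.242, Esrrb -0.017 to 0. In the knock-out: Ctnnb1 -0.245 to 0.186, Gsk3a -0.078 to 0.071 (0.009 with the stricter filter), Lef1 -0.854 to 0.77, Esrrb -0.048 to 0.044 (0.012 with the stricter filter, 0.003 with the compared groups). For the knock-out in DMSO: Gsk3a -0.024 to 0.131, Jup -0.049 to 0.046 (0.011 with the stricter filter), Tcf7 -0.041 to 0.079, Lef1 -0.67 to 0.324, T -0.492 to 0.677 (0.076 with limma-voom). In CHIR99021: Gsk3b -0.013 to 0.083, Lef1 -0.915 to 0.707 (-0.11 with limma-voom). For the interaction: Ctnnb1 -0.131 to 0.295, Gsk3a -0.107 to 0.047, Lef1 -0.829 to 0.79, Esrrb -0.045 to 0.051, Pou5f1 -0.039 to 0.039.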

Other observations

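Tests in this part chosen only after the result was seen are those on loss of the Y chromosome and on Ddx3y and Ddx3x in CHIR99021, and so was the limit of the copy number test to the CHIR99021 libraries.

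Regulators downstream of BMP split in parental cells: with CHIR99021 Id2 fell by 2.16 on the log2 scale, from 15.3 ± 0.912 to 3.41 ± 0.383 CPM (SD, n = 2 each), while its relatives Id3 and Id1 rose by 1.14 ± 0.11 (SE) and 0.31 ± 0.06, and the BMP list as a whole did not pass (4 higher and 3 lower of 13; adjusted over the list alone 4 and 4; adjusted p = 0.777). Genes of the Wnt pathway itself went both ways, 6 higher and 11 lower of 46 (adjusted over the list alone 9 and 12; adjusted p = 0.739), with Porcn at 1.29 ± 0.06 and the secreted inhibitor Sfrp1 at -0.90 ± 0.04. Of 23 genes of the cadherin-catenin junction 5 fell and none rose, also adjusted over the list alone (adjusted p = 0.123), P-cadherin (Cdh3) by 1.42. Among 25 imprinted genes 4 rose and 6 fell (adjusted over the list alone 5 and 6; adjusted p = 0.284): Cdkn1c fell by 1.70, Mest by 0.77 and Peg3 by 0.70 on the log2 scale, and Grb10 rose by 0.55 ± 0.04. In the knock-out Cdkn1c fell by 0.66 and Grb10 rose by 0.38 ± 0.05; the response differed for Cdkn1c, by 1.04 ± 0.09. Without CHIR99021, the knock-out had lower Grb10 (-0.84 ± 0.05) and higher Igf2 (0.94 ± 0.14) than parental cells.

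With camera and the preset correlation, 10 lists showed no call in any comparison, among them several for other cell types. The trophoblast, extraembryonic endoderm, definitive endoderm and neural ectoderm lists did have calls, as given above. The lowest adjusted p over the 5 comparisons was 0.062 for blood and endothelium, 0.126 for heart and smooth muscle, 0.203 for mesenchyme and fibroblasts, 0.13 for surface epithelium, 0.353 for Hox genes and 0.675 for germ line genes. It was 0.0565 for imprinted genes, 0.0827 for the cadherin-catenin junction, 0.209 for Wnt pathway components and 0.0971 for the BMP response. Imprinted genes passed in the knock-out with CHIR99021 without parental CHIR99021 replicate 1 (0.0434), replicate 2 (0.045) or knock-out DMSO replicate 1 (0.00675), and blood and endothelium for the knock-out in DMSO without parental DMSO replicate 1 (0.0252) or the distal genes of chromosomes 1 and 2 (0.0427). Fry, which does not compare a list with other genes, called several of these lists. In parental cells with CHIR99021 they were surface epithelium (adjusted p = 0.00227), blood and endothelium (0.0455) and the cadherin-catenin junction (0.00152), lower, and mesenchyme (0.0275) and Hox genes (0.0336), higher. In the knock-out with CHIR99021 surface epithelium (0.009), the cadherin-catenin junction (0.00829) and the BMP response (0.0402) were lower. For the knock-out against parental cells, blood and endothelium (0.0196 in DMSO, 0.0105 in CHIR99021), heart and smooth muscle (0.0133 and 0.00722) and, in CHIR99021, surface epithelium (0.0144) were higher. Of 19 genes of the two-cell-like state 3 were measured, too few to test, and none was called. The Y-linked list passed for CHIR99021 in the knock-out with 1 of 6 called higher (adjusted over the list alone, 5; adjusted p = 0.00855, and adjusted p = 0.259 with an estimated correlation; 0.0848 without knock-out DMSO replicate 1).

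Genes of distal chromosome 2 were lower and genes of distal chromosome 1 higher in the knock-out. Removing trends on GC content, transcript length and expression level left the chromosome 2 median in DMSO at -0.208, which argues against such a trend. A candidate explanation is a copy number of these segments that differs between the lines. It was tested in the CHIR99021 libraries, which had no part in finding the segments. The median nearest 0 over all their genes and over the low, middle and high ones by expression was -0.151 for chromosome 2 and 0.128 for chromosome 1, past the limits set for that hypothesis. The CHIR99021 libraries come from the same lines, so any lasting difference between the lines along a segment would repeat in them. The test thus shows that the shifts persist and cannot tell copy number from other such differences. On chromosome 1, however, the shift shrank with expression level. It was 0.278, 0.191 and 0.128 in the low, middle and high genes in CHIR99021, and 0.219, 0.178 and 0.137 in DMSO. The test did not weigh this gradient. The median ratios in DMSO, 0.867 and 1.12, are smaller than a whole gained or lost copy in each cell would give, so only part of the cells may carry such a change. DNA was not measured. On the other chromosomes, each split in the same way, the parts had medians of -0.127 to 0.058 in DMSO and -0.057 to 0.063 in CHIR99021.

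Y-linked genes were higher in the knock-out. Loss of the Y chromosome from part of the parental cells would raise them there by a like fold, and the difference of 0.335 (SE 0.0779) between the log2 fold changes of Uty and Eif2s3y in DMSO argues against it as the whole cause. Uty was higher by 25.5 CPM and its X-linked copy Kdm6a changed by -1.86 CPM, while Eif2s3y was higher by 31.3 CPM and Eif2s3x changed by -18.6 CPM; reads that Eif2s3y took from that copy would make its own rise smaller and the difference larger. Reads shared with the X-linked copy Ddx3x were weighed for Ddx3y. In DMSO Ddx3x fell by 95 CPM against a rise of 68.1 CPM in Ddx3y, a share of 1.39. The sum of both changed by -26.9 CPM with an SD of 13.7, within 2 SD, as sharing needs. In CHIR99021 Ddx3x fell by only 19.6 CPM against a rise of 82.6 CPM, a share of 0.238. The log2 fold change of Ddx3y was alike, 1.77 against 1.70 in DMSO. The change of the sum, 63 CPM with an SD of 31.6, was again within 2 SD. Both sums lay close to that limit with 2 libraries per group, so whether shared reads account for Ddx3y stays open. A difference between the lines that goes with their derivation stays open and was not tested.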
